A study of Mus musculus with 23 samples.

How the data were processed

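Poly-A RNA of infarct scars was sequenced in 14 libraries, 8 from control mice and 6 from mice given Treg-polarized TCR-M cells, and samples were grouped by their labels. Reads were trimmed with cutadapt 2.5, aligned with STAR 2.7.2b and assigned with featureCounts 1.6.4 of Subread, per the submitters' processing notes, which also name DESeq2 1.24.0. The deposited scar table holds estimated counts, since reads shared between genes were counted in parts: 88.7% of values were exactly whole, with no tolerance. The design had assumed whole counts, so the values were rounded to whole numbers before testing. Coordinates are those of the table, on GRCm39.

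Single cells and receptors were processed with Cell Ranger 6.0.1 (transfer libraries) and 7.0.0 (library without transfer), per the submitters' processing notes. The deposited single-cell matrix holds UMI counts per gene and antibody tag, and the contig tables hold UMI counts per receptor chain. The deposited clonotype tables give each clonotype as a fraction of the cells with a receptor. Which hashtag marks which mouse in the transfer libraries is not given in the sources used here, so these were not divided by tissue or day.

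Scar genes were kept by the filterByExpr function of edgeR (16126 of 46320 genes) and scaled by trimmed mean of M values (TMM). Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM used a prior count of 2. Of 31 gene lists written before the data were examined, 30 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. List members were also adjusted over the list alone.

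Alternatives planned before the data were examined were 3 other scalings, 2 other filters, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom with and without sample quality weights, and 2 other thresholds. Chosen after the data were seen were a robust fit, a covariate for muscle content (the mean log2 CPM of the contractile list), control 2 and transfer 2 left out together, other clustering genes, and DESeq2, limma-voom and the covariate with control 2 left out. A rerun counting control 2 with the transfer libraries was made once and dropped, since it groups a sample by its outcome. The real grouping and other random splits of the libraries made up 100 splits, with seed 11 for 14 libraries and seed 12 for 13.

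Genes named in the scar are the 10 highest and 10 lowest past the threshold by log2 fold change with a mean log2 CPM of at least 1, up to 4 members of each list with the smallest p (2 where none passes), and 11 genes fixed in advance. For each pair of cell pools they are the 8 highest and 8 lowest ratios among genes with at least 50 counts in the pair, 20 CPM in the higher pool and an interval without 1, plus 14 fixed genes. Gene models without a symbol and receptor segments were not named, and some genes of this rule are not reported here.

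Barcodes with at least 200 genes and under 10% mitochondrial counts were kept. A cell was given to a pool when exactly 1 hashtag lay above a threshold from a mixture of 2 components. The 129 barcodes with more than 1 such hashtag were left out as doublets, no doublet caller was run, and doublets within a pool stay in. Clusters came from scanpy 1.11.5 with 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1, and were named by marker lists fixed in advance (at least 3 markers found in 10% of cells, 2 of them among the top 10 genes). Median depth was 6937 UMIs per cell in sham lymph nodes, 6955 in infarct lymph nodes and 5679 in infarcted hearts. Ratios of summed counts have exact 95% intervals, and 0 counts were set against a floor of 3. Clonotypes were defined by both V genes and both CDR3 nucleotide sequences in cells with 1 alpha and 1 beta chain, and expanded ones hold at least 2 cells. Shares at equal cell numbers are means of 1000 draws. Python 3.11.15, scipy 1.17.1 and scikit-learn 1.9.0 were used.

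The methods were tested on simulated data. With 200 changed genes in 14 libraries, 10.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 87.9% of those changed 4-fold were called, with 2 false among 102 calls. With 13 libraries these were 20.9%, 64.2% and 100%, with 5 false among 128. Simulated ratios lay inside their intervals in 96.95%, 96.3% and 95.8% of 2000 draws. The simulated genes were drawn independently of each other, while the first principal component of the scar libraries held 67.6% of variance. The simulated ratios were drawn without cells that hold a large share of the counts. The false calls and the coverage therefore do not carry over to data with such structure. Libraries were checked against their labels by sex-linked genes, and 0 libraries did not match their group. This check cannot see labels exchanged between animals of 1 sex.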

Results

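Infarct scars, heart and lymph node CD4 T cells and their receptors were measured in mice with experimental myocardial infarction. In the scar series, messenger RNA was sequenced from scars taken on day 5 from 8 control mice that received no T cells and from 6 mice that received TCR-M cells polarized to regulatory T cells (Treg). TCR-M cells are CD4 T cells that carry a transgenic receptor for cardiac myosin. Reads assigned to genes ranged from 17604010 (control 2) to 29609012 (control 3) per library. In the single-cell series, 1 library of CD4 T cells sorted from hearts and mediastinal lymph nodes of mice without transfer gave gene counts, hashtag counts and receptors for 3067 barcodes. Receptors were also sequenced in 2 technical libraries of 1 pooled sample from mice with TCR-M transfer.

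The first comparison asked which genes differed in the scar after transfer of Treg-polarized TCR-M cells. Among the genes that rose were the muscle genes Myot and Abra and the genes Crispld1 and Cxcl12, whose products are secreted. Myot (gene ID 58916; GRCm39 chromosome 18, 44467126 to 44488795), which encodes a Z-disc protein of striated muscle, stood at 2.91 ± 0.67 log2 CPM in controls (mean ± SD, n = 8) and 4.76 ± 0.72 after transfer (n = 6). The muscle gene Abra, which encodes an actin-binding protein, stood at 5.42 ± 0.34 and 6.64 ± 0.39. The secreted protein gene Crispld1 (gene ID 83691; chromosome 1, 17797255 to 17840350) stood at 0.14 ± 0.41 and 1.86 ± 0.39. The chemokine gene Cxcl12 (gene ID 20315; chromosome 6, 117145496 to 117158329), whose product binds the receptor Cxcr4, stood at 7.39 ± 0.22 and 8.11 ± 0.25. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, the log2 fold changes (± SE) were 1.90 ± 0.33 for Myot (adjusted p = 0.0431), 1.23 ± 0.18 for Abra (adjusted p = 0.0177), 1.78 ± 0.23 for Crispld1 (adjusted p = 0.0173) and 0.72 ± 0.13 for Cxcl12 (adjusted p = 0.0463). Other genes that rose were Armh4 (1.00 ± 0.14), the peptide-amidating enzyme gene Pam (0.92 ± 0.16), the salt-inducible kinase gene Sik1 (0.89 ± 0.12), the fucosidase gene Fuca2 (0.88 ± 0.16), the co-chaperone gene Dnajb4 (0.76 ± 0.13) and the monooxygenase gene Fmo1 (0.73 ± 0.12), with adjusted p between 0.0173 (Armh4, Sik1) and 0.0457 (Fuca2) in edgeR.

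Among the genes that fell were Pycard, Arhgap9 and Bcl2l11. Pycard (gene ID 66824; chromosome 7, 127590545 to 127593039), which encodes the inflammasome adaptor ASC, stood at 4.04 ± 0.74 log2 CPM in controls (n = 8) and 2.7003 ± 0.23 after transfer (n = 6). Arhgap9 (gene ID 216445; chromosome 10, 127157829 to 127165816), a signalling gene of blood cells, stood at 4.57 ± 0.51 and 3.27 ± 0.30, and Bcl2l11, which encodes the pro-apoptotic protein Bim, at 4.82 ± 0.33 and 3.601 ± 0.452. In edgeR the log2 fold changes (± SE) were -1.47 ± 0.27 for Pycard (adjusted p = 0.0457), -1.34 ± 0.22 for Arhgap9 (adjusted p = 0.0306) and -1.19 ± 0.20 for Bcl2l11 (adjusted p = 0.0387). Also lower were the lysosomal transporter gene Mfsd12 (-1.66 ± 0.31), the DNA translocase gene Zranb3 (-1.63 ± 0.30), the adenine salvage enzyme gene Aprt (-1.31 ± 0.23), the kinase gene Cdk20 (-1.26 ± 0.22), the nucleotide hydrolase gene Dnph1 (-1.08 ± 0.20), the peroxisomal transporter gene Abcd2 (-1.02 ± 0.19) and Tmem86a (-0.95 ± 0.14), with adjusted p between 0.0173 (Tmem86a) and 0.0463 (Zranb3) in edgeR.

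Of 16126 genes tested in edgeR, 33 passed: 16 rose and 17 fell, and 2854 had an unadjusted p under 0.05. In each of the 16 genes that rose, all 6 transfer libraries lay above every control. Of the 17 that fell, all 6 lay below every control in 9 and below every control but control 2 in the other genes. The p-values measure the spread between samples. The count rests on single libraries: without controls 1 to 8 it was 2, 4534, 7, 9, 8, 9, 7 and 0 genes, and without transfers 1 to 6 it was 3, 9, 0, 0, 5 and 61. Where it was 0, unadjusted p under 0.05 was found for 2211 (control 8), 2695 (transfer 3) and 2211 genes (transfer 4). Without control 2, 2508 genes rose and 2026 fell, and all 33 genes kept their sign and their call. DESeq2 called 1051 genes, of which 410 rose and 641 fell, limma-voom 20, and limma-voom with sample quality weights 4717. Without scaling beyond the read total edgeR called 0 genes, with 3159 at an unadjusted p under 0.05 and the median of all genes shifted to -0.11. With no filter beyond 1 count it called 4, all higher, and with at least 1 CPM in 6 libraries 69.

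**Figure D1:**
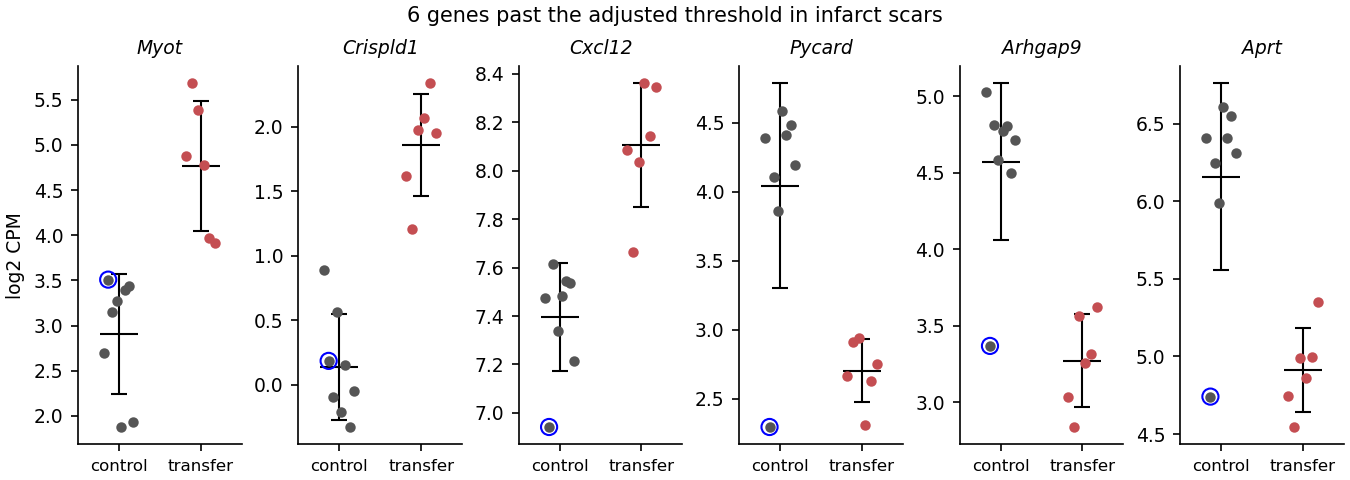
Log2 CPM (y axes) of 6 genes past the adjusted threshold in each scar library, controls (n = 8) beside transfer (n = 6), with mean and SD as lines and control 2 circled. The 6 transfer libraries lie above every control for Myot, Crispld1 and Cxcl12, and below every control except control 2 for Pycard, Arhgap9 and Aprt.

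Control 2 stood apart from the other scars in its tissue genes. Its fibroblast matrix score (mean log2 CPM of the list) was 3.44, against 5.41 to 9.07 in the other 13 libraries, and its cardiomyocyte contractile score was 12.05, against 9.05 to 11.76. It held 2526 reads of the collagen gene Col3a1, and 12 reads of Spp1, the gene of the secreted matrix protein osteopontin. The mean reparative macrophage score was 6.76 ± 1.08 in controls (n = 8) and 6.07 ± 0.58 after transfer (n = 6), and in control 2 it was 4.12.

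**Figure D2:**
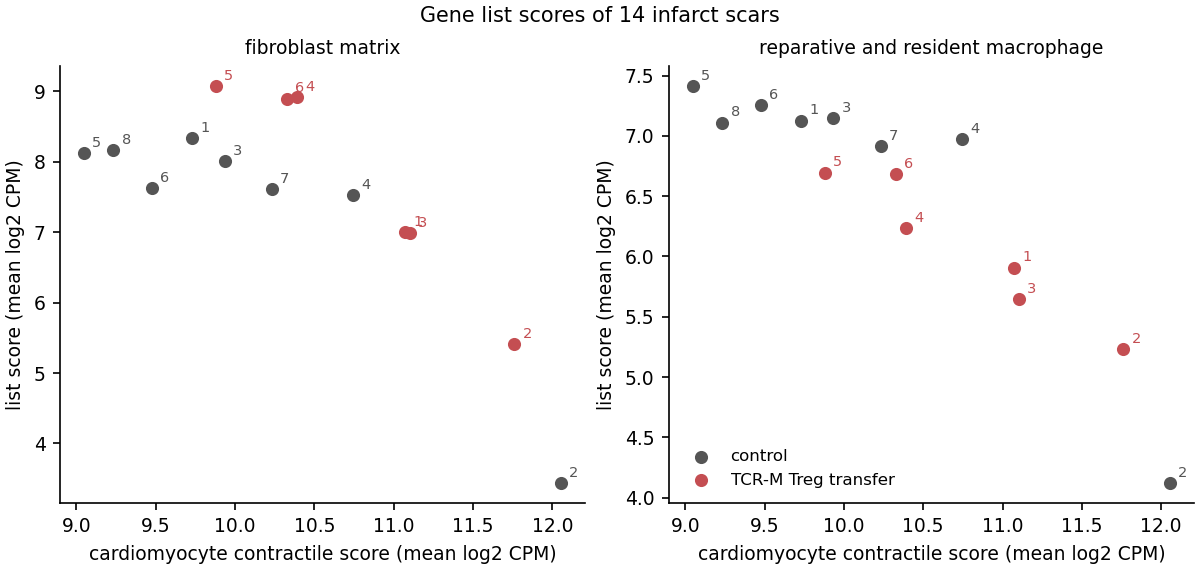
Gene list scores (mean log2 CPM) of the 14 scars, with the cardiomyocyte contractile score on the x axes and the fibroblast matrix score (left) or reparative macrophage score (right) on the y axes; each point is 1 library, numbered by replicate. Control 2 has the highest cardiomyocyte score, 12.05, and the lowest score of both other lists, 3.44 and 4.12.

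At the preset correlation, gene groups of working heart muscle were shifted upward after transfer, relative to all other genes. Most random splits of the libraries called at least as many lists, so the list calls in this and the next paragraphs are not told apart from chance. The cardiomyocyte contractile list (24 members tested; median log2 fold change 0.51), oxidative phosphorylation (25 members; 0.42), fetal and wall-stress genes (10 members; 0.68) and fatty acid oxidation (20 members; 0.27) had adjusted p of 0.00145, 0.00145, 0.00157 and 0.00600 in limma camera. With an estimated correlation the adjusted p was 0.815 for the fetal list and 0.884 for the other 3. In none of the 4 lists did a single member pass over all genes in edgeR. Adjusted over the list alone, 4 fetal and wall-stress genes were higher and 0 members of the other 3 lists. Examples were skeletal actin Acta1 at 0.90 ± 0.29, the natriuretic peptide gene Nppb at 0.88 ± 0.24, the calcium-storage gene Casq2 at 0.75 ± 0.39, the myosin-binding gene Mybpc3 at 0.49 ± 0.28, the respiratory chain gene Uqcrc2 at 0.49 ± 0.38 and Cpt1b, of fatty acid import into mitochondria, at 0.50 ± 0.48 (log2 fold change ± SE). In fry, the lowest adjusted p was 0.0540 for the fetal list and 0.666 for the other 3. Without transfer 2, the library with the highest cardiomyocyte score after control 2, the fatty acid oxidation median was 0.03 (adjusted p = 0.137) and the oxidative phosphorylation median 0.22 (adjusted p = 0.0528) in camera. With a covariate for muscle content, chosen after the data were seen, the calls ended for contractile genes (median 0.02; the covariate is their own mean), oxidative phosphorylation (-0.042) and fatty acid oxidation (-0.10), and the fetal list kept its call (0.59) until control 2 was left out as well (0.41).

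Vessel lists were also shifted upward. The endothelial list (24 members; median 0.28; adjusted p = 0.0196 in camera) and the pericyte and smooth muscle list (12 members; 0.31; adjusted p = 0.0329) had 0 members past the threshold over all genes in edgeR, and 3 and 2 higher adjusted over the list alone. With an estimated correlation both had an adjusted p of 0.884, and in fry 0.650 and 0.481. The receptor genes of vascular endothelial growth factor were examples, with Kdr at 0.80 ± 0.19 and Flt1 at 0.70 ± 0.16, as were the mural cell genes Vtn at 0.84 ± 0.24 and Steap4 at 0.80 ± 0.23. Both calls ended without control 2 (medians 0.19 and 0.26), transfer 4 (0.13 and 0.25), transfer 5 (0.16 and 0.26) or transfer 6 (0.12 and 0.31). With the muscle covariate both stayed called (0.40 and 0.45), also without control 2 (0.35 and 0.41).

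Neutrophil and cell cycle genes were shifted downward. The neutrophil list (11 members tested; median -1.34; adjusted p = 0.00157 in camera) held 0 members past the threshold over all genes in edgeR and 5 lower adjusted over the list alone. With an estimated correlation its adjusted p was 0.884, and in fry 0.481. Examples were the collagenase gene Mmp8 at -1.65 ± 0.54 and the secreted resistin-like gene Retnlg at -1.40 ± 0.42. The cell cycle list (30 members; median -0.61; adjusted p = 0.00212) held 0 by either count, with the replication genes Mcm5 at -0.88 ± 0.38 and Pcna at -0.53 ± 0.18. With an estimated correlation its adjusted p was also 0.884, and in fry 0.666. With the muscle covariate both calls ended, with medians of -0.43 and 0.030, and all 8 lists then called in camera pointed up. Control 2 had low values in both, a neutrophil score of -0.26 and a cell cycle score of -0.01.

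The other immune lists did not pass over all libraries. Medians were -0.82 for general T cell genes and -0.55 for MHC class II presentation (adjusted p = 0.0668 for each in camera), -0.49 for reparative macrophages (adjusted p = 0.0668), -0.65 for inflammatory monocytes and macrophages (adjusted p = 0.104), -0.66 for cytotoxic and NK cells (adjusted p = 0.263), -0.57 for B and plasma cells (adjusted p = 0.386), -0.14 for dendritic cells (adjusted p = 0.386), -0.22 for chemokines (adjusted p = 0.529) and -0.01 for the interferon response (adjusted p = 0.828). With an estimated correlation the adjusted p lay between 0.884 (T cells) and 0.951 (interferon response). Adjusted over the list alone, 6 reparative macrophage genes were lower and 1 higher, and likewise 6 and 1 inflammatory genes, 3 and 1 chemokine genes, 1 and 0 dendritic genes, and 0 in the T cell, MHC class II, cytotoxic, B cell and interferon lists. Over all genes only the chemokine gene Cxcl12 passed in these lists. Examples were the lipid-binding gene Fabp5 at -2.24 ± 0.53, the folate receptor gene Folr2 at -1.005 ± 0.246, the chemokine genes Ccl3 at -1.97 ± 0.60, Ccl4 at -1.72 ± 0.50 and Pf4 at -1.46 ± 0.38, the interleukin 7 receptor gene Il7r at -2.95 ± 0.89 and the monocyte gene Ly6c2 at 0.59 ± 0.16. In camera the T cell list was called without controls 2 and 7 and transfers 1 and 5 (medians -0.93, -0.85, -1.03 and -0.96). The reparative macrophage list was called without controls 2 and 7 and transfer 5 (-0.58, -0.49 and -0.66), MHC class II without controls 2 and 7 (-0.66 and -0.57), and the inflammatory and chemokine lists without control 2 (-0.78 and -0.22). With the muscle covariate none of these lists was called, and the medians were positive for reparative macrophages (0.06), inflammatory cells (0.05), chemokines (0.46), dendritic cells (0.29) and the interferon response (0.22).

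Leaving out each library in turn was planned before the data were examined, but control 2 was singled out after its result was seen. Control 2 had a higher cardiomyocyte score than any transfer library, so its removal itself widens the difference in muscle genes. Without control 2, more members passed in both directions in edgeR. Over all genes, 14 of 24 cardiomyocyte, 14 of 20 fatty acid oxidation, 21 of 25 oxidative phosphorylation and 4 of 10 fetal and wall-stress genes rose. On the lower side were 12 of 22 reparative macrophage genes, 9 of 25 chemokine, 7 of 17 inflammatory macrophage, 7 of 11 neutrophil, 7 of 30 cell cycle, 5 of 12 MHC class II and 4 of 15 T cell genes, with 2, 1, 1, 0, 0, 0 and 1 higher. The reparative genes that fell include Fabp5 at -2.38 ± 0.29 and Folr2 at -1.11 ± 0.13, and the MHC class II genes include the protease gene Ctss at -1.90 ± 0.41. Camera then called 11 lists, 4 up and 7 down, and with an estimated correlation 0, with a lowest adjusted p of 0.644. The medians of the 4 heart muscle lists were 0.96, 1.05, 0.92 and 0.81 in the order given. With the muscle covariate as well, the lower members were 5 reparative macrophage, 2 chemokine, 4 inflammatory macrophage, 1 neutrophil, 0 cell cycle, 0 MHC class II and 1 T cell gene, and 0 members of the 4 heart muscle lists rose in edgeR.

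Matrix and remodelling lists did not pass without a covariate. The fibroblast matrix list (36 members) had a median of 0.51 (adjusted p = 0.138 in camera), with the collagen-binding genes Dcn at 0.79 ± 0.24 and Lum at 0.87 ± 0.36, and it was called without control 1 (0.63), control 5 (0.57) and transfer 2 (0.78). The transfer group was divided in its fibroblast matrix score. It was 7.00, 5.41 and 6.99 in transfers 1 to 3 and 8.92, 9.07 and 8.89 in transfers 4 to 6. In controls other than control 2 it was 7.52 to 8.33. What divides the transfer libraries was not tested. The myofibroblast list had a median of -0.03 (adjusted p = 0.575), matrix proteases and inhibitors -0.11 (adjusted p = 0.799) and TGF-beta and activin genes 0.19 (adjusted p = 0.517), and with an estimated correlation the adjusted p was 0.900 to 0.951 for these 4 lists. Adjusted over the list alone, 4 matrix protease genes were lower and 1 higher, among them the collagenase gene Mmp13 at -1.36 ± 0.29 and Adam19 at 0.50 ± 0.15, and 0 in the other 3 lists. With the muscle covariate camera called the fibroblast matrix list at the preset correlation (median 1.34; 10 members higher over all genes), TGF-beta and activin genes (0.63; 5), matrix proteases (0.47; 3), myofibroblasts (0.43; 1) and the immediate early list (0.50; 3). With control 2 left out as well it called 7 lists, 5 up and 2 down. Up were the first of these (1.18; 2 members), TGF-beta (0.68; 1), immediate early (0.44; 2) and the 2 vessel lists, and down were reparative macrophages (-0.22; 5 members lower) and red blood cells (-1.15; 0). The covariate was not run with an estimated correlation. The glycolysis and hypoxia list had a median of 0.25 (adjusted p = 0.0668), with Vegfa at 0.85 ± 0.26, and it was called without control 5 (0.27) and control 7 (0.32). The immediate early list had a median of 0.22 (adjusted p = 0.193), with 1 member higher adjusted over the list alone and Nr4a1 at 1.54 ± 0.33, and it was called without transfer 2 (0.39). Lists of tissue that could be carried over gave 0.43 for adipocytes (3 members; adjusted p = 0.0783), -1.39 for epicardium and mesothelium (0.104), 0.06 for Schwann cells and nerve (0.661), -0.03 for red blood cells (0.517) and -0.57 for skeletal muscle (0.575). For lymph node stroma (3 members; 0.408) the test pointed up while the median, -0.69, and mean, -0.40, were negative. The epicardial list was called without control 7 (-1.54), and adjusted over the list alone 1 nerve gene was higher (Cdh19 at 0.77 ± 0.23) and 1 lower (Mbp at -0.99 ± 0.21).

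Genes of regulatory T cells were near the detection limit in the scar. Foxp3, the Treg transcription factor gene, had 23 reads over the 8 controls and 11 over the 6 transfer libraries. Ctla4 had 13 and 11 and the cytokine gene Il10 had 72 and 21, and all 3 were too low to be tested. The interleukin 2 receptor gene Il2ra differed by 0.06 ± 0.30 (adjusted p = 0.931 in edgeR), Cd4 by -0.45 ± 0.48 (adjusted p = 0.655), Cd3e by -0.82 ± 0.64 (adjusted p = 0.531), Thy1 by -0.42 ± 0.48 (adjusted p = 0.669) and Tgfb1 by -0.36 ± 0.25 (adjusted p = 0.486). The Treg list (7 of 15 members tested) had a median of 0.07 and a mean of -0.17, and the camera test pointed down (adjusted p = 0.828, and 0.938 with an estimated correlation). The effector T helper list had too few members for a test, with the chemokine receptor gene Cxcr3 at -1.05 ± 0.61. Col1a1 differed by 0.67 ± 0.73 (adjusted p = 0.659), Myh6 by 0.64 ± 0.76 (adjusted p = 0.687) and Arg1 by -0.42 ± 0.91 (adjusted p = 0.830). The Col1a1 mean hides a divided transfer group. Transfers 1 to 3 stood at 9.75, 8.33 and 9.43 log2 CPM, and transfers 4 to 6 at 12.62, 12.50 and 12.42. Controls other than control 2 lay between, at 10.74 to 11.62.

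The next comparisons set CD4 T cells of heart and lymph node side by side, after sham surgery or infarction and without transfer. Of 3067 barcodes, 3064 passed the cell filter, and 2815 of these carried exactly 1 hashtag above its threshold: 723 from lymph nodes after sham surgery, 1911 from lymph nodes after infarction, 181 from infarcted hearts and 0 from sham hearts. All 38 barcodes positive for the sham heart tag also carried the infarcted heart tag above its threshold. When the top hashtag had to hold at least 75% of hashtag counts, 30 cells were assigned to sham hearts. Median depth was 6937, 6955 and 5679 UMIs per cell in the 3 filled pools. Each pool is 1 sample, so no test was made between them, and intervals are 95% and hold counting error only.

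T cells with Foxp3 transcripts made up a larger share in infarcted hearts than in lymph nodes. At least 1 Foxp3 UMI was found in 12.2% of infarcted heart cells (22 of 181; interval 7.78 to 17.8), in 6.17% of lymph node cells after infarction (118 of 1911; 5.14 to 7.35) and in 5.39% after sham surgery (39 of 723; 3.86 to 7.30). In the naive-like lymph node cluster, which should lack Foxp3, it was 0.743% after infarction (2 of 269; median depth 7490 UMIs) and 2.27% after sham surgery (2 of 88; 7311 UMIs). For the heart this background is not measured, since its part of that cluster is 1 cell. Thinned to 2000 UMIs per cell the shares were 7.74% (4.18 to 12.9), 3.76% (2.94 to 4.73) and 3.41% (2.20 to 5.04). At 1000 UMIs they were 4.49% (1.96 to 8.66), 2.63% (1.96 to 3.45) and 1.67% (0.864 to 2.89). In these pools, heart and infarct lymph node intervals overlap at both depths. With pools from the 75% rule they overlap at 2000 UMIs, at 7.60% (4.11 to 12.6) and 3.78% (2.97 to 4.74). At 1000 UMIs that rule gave 7.14% (3.86 to 11.9) and 2.697% (2.03 to 3.51), without overlap. Whether the intervals overlap at 1000 UMIs thus differed between the rules. Before thinning, the 2 rules gave nearly the same infarcted heart counts, 22 of 181 and 23 of 185 cells with Foxp3. Each thinning was a single random draw, run separately for each rule. The noise of the draw and the assignment to pools are therefore not told apart. Among the 30 cells assigned to sham hearts by the 75% rule, 3 had a Foxp3 UMI (10.0%; 2.11 to 26.5).

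**Figure D3:**
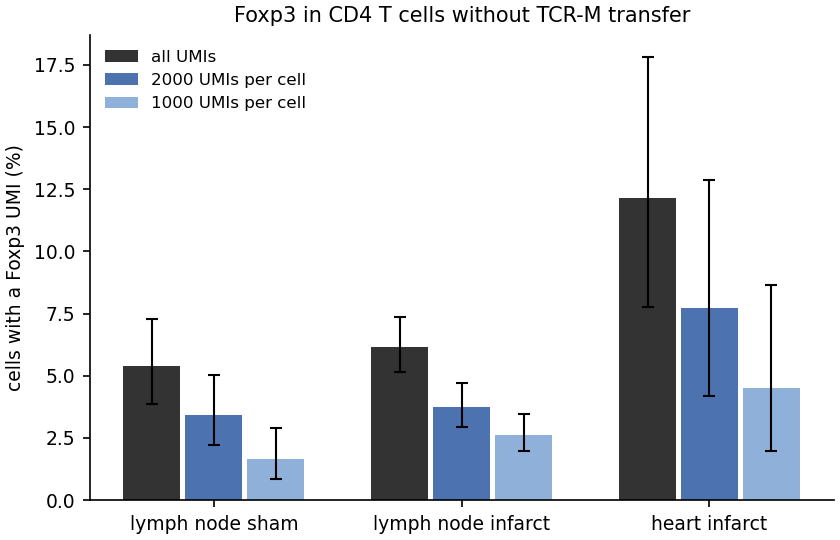
Share of CD4 T cells with at least 1 Foxp3 UMI (y axis, percent) in 3 pools without transfer, with all UMIs and after thinning each cell to 2000 or 1000 UMIs; error bars are exact binomial 95% intervals. The infarcted heart share is 12.2% with all UMIs and 4.49% at 1000 UMIs.

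The share of cells in the Treg-like cluster was similar in the 3 pools, 8.84% in infarcted hearts (16 of 181; 5.14 to 13.96), 8.42% in lymph nodes after infarction (161 of 1911; 7.22 to 9.76) and 8.44% after sham surgery (61 of 723; 6.51 to 10.7). The heart value depends on the clustering, with 39.2% at Leiden resolution 0.5, 0.552% at resolution 1.5 and 2.16% with pools from the 75% rule. Of the 16 heart cells in the cluster, 15 had a Foxp3 UMI, at a median depth of 10246.5 UMIs. In lymph nodes it was 92 of 161 after infarction (6625 UMIs) and 29 of 61 after sham surgery (6953 UMIs), so depth differs too. Other clusters were not similar between pools. The Th1-like cluster held 57 infarcted heart cells, 27 infarct and 3 sham lymph node cells. An unnamed cluster led by Hspa1a held 55, 1 and 0 in that order, and the naive-like cluster 1, 269 and 88. The tag for the myosin tetramer had more than 9 counts in 4.97% of infarcted heart cells (9 of 181; 2.30 to 9.23), 2.20% of lymph node cells after infarction (42 of 1911; 1.59 to 2.96) and 0.830% after sham surgery (6 of 723; 0.305 to 1.80), where 9 counts is the 99th percentile. At the 95th percentile the shares were 10.5%, 5.18% and 3.32%. At the highest percentile tried they were 0% (0 of 181 cells, which allows up to 1.66%), 0.105% (2 of 1911) and 0.138% (1 of 723), too few cells for an order.

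Infarcted heart T cells had higher summed CPM of Hspa1a, Ifng, Gzmb and Foxp3 than lymph node T cells after infarction, and lower ones of Tcf7, Dapl1 and Ccr7. Ratios of summed CPM, heart over lymph node, were 755 for the heat shock gene Hspa1a (573 to 1016; counts in 97 heart cells) and 694 for Hspa1b (550 to 889). They were 211 for interferon gamma, Ifng (108 to 470; 14 cells), 203 for granzyme B, Gzmb (108 to 431; 11 cells), 135.4 for the chemokine gene Ccl5 (103 to 182; 11 cells), 274 for the surface antigen gene Ly6c2 (123 to 759.7; 7 cells), 181 for Fgl2 and 169 for the leukotriene receptor gene Ltb4r1. Treg-linked genes stood at 4.73 for Foxp3 (4.00 to 5.59), 5.33 for Il2ra (4.51 to 6.27), 2.45 for Ctla4, 2.98 for Ikzf2, 2.05 for Tnfrsf18, 88.4 for the interleukin 33 receptor gene Il1rl1 (52.2 to 159.7; 17 cells) and 17.1 for amphiregulin, Areg (12.7 to 23.2; 10 cells). Several of these ratios rest largely on single heart cells, as the top cell of each gene held 48.6% of the counts for Areg, 42.7% for Ifng, 32.7% for Gzmb, 32.1% for Il2ra, 30.9% for Ly6c2 and 30.2% for Ccl5, against 16.2% for Il1rl1 and 14.2% for Foxp3. Whether these are the same cells was not examined. The activation gene Cd44 stood at 1.53 and the cycling gene Mki67 at 1.19 (0.775 to 1.75). Cells with a Mki67 UMI made up 7.73% of infarcted heart cells (14 of 181; 4.29 to 12.6) and 0.942% of lymph node cells (18 of 1911; 0.559 to 1.48). Interleukin 17A, Il17a, had 13 counts in 2 heart cells and 0 in lymph nodes, at least 52.4-fold higher against a floor of 3 counts over the pool (lower limit of the interval 36.8), but 1 cell held 69.2% of these counts. Lower in the heart were the lymph node homing gene Ccr7 at 0.440 (0.406 to 0.476), the naive T cell factor gene Tcf7 at 0.747, Dapl1 at 0.124 (0.0775 to 0.188), Dtx1 at 0.137, Maip1 at 0.198, the histone gene Hist1h1b at 0.248, Khdrbs3 at 0.318, Ephx1 at 0.339, and P2ry10b and Ttc27 at 0.346 each.

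Lymph node T cells after infarction had higher summed CPM of Mki67, Hist1h1b and Foxp3 than after sham surgery, and lower ones of Iigp1, Gbp6 and Tgtp2. The proliferation gene Mki67 had a ratio of 8.74 (4.92 to 17.1), from 18 cells after infarction and 6 after sham surgery, and the histone gene Hist1h1b 21.5 (9.10 to 66.7; 15 and 5 cells). Both ratios rest on few cells, as the top cell of each gene held 22.1% of the Mki67 and 40.8% of the Hist1h1b counts after infarction, and the share of cells with Mki67 was 0.942% after infarction (0.559 to 1.48) and 0.830% after sham surgery (0.305 to 1.80). Other high ratios were 4.90 for Hist1h2ae, 4.63 for Ehbp1 (395 and 32 cells), 3.12 for the calcium-binding gene S100a6, 2.66 for Hist1h2ap, 1.70 for topoisomerase Top2a and 1.64 for Foxp3 (1.33 to 2.03). Of these the top cell held 35.3% of the counts for S100a6 (44 and 7 cells), 32.8% for Hist1h2ae, 28.5% for Top2a, 20.1% for Hist1h2ap, 3.78% for Foxp3 and 0.924% for Ehbp1. Il2ra stood at 1.53, Ikzf2 at 1.37, Ctla4 at 1.27, Cd44 at 1.04, Tnfrsf18 at 0.989, Tcf7 at 0.987 and Ccr7 at 0.983. Lower after infarction were the interferon-induced GTPase genes Iigp1 at 0.401 (0.3295 to 0.487), Gbp6 at 0.582 (0.485 to 0.699) and Tgtp2 at 0.669 (0.576 to 0.779), with Spata7 at 0.456, Fhit at 0.565, Klhl11 at 0.641, Castor1 at 0.662, Ctsw at 0.671, Areg at 0.443 (0.314 to 0.627) and Ifng at 0.237 (0.0903 to 0.587; 2 cells in each pool). Il1rl1 had 16 counts against 3 (ratio 1.96; 0.562 to 10.5), and 1 cell held most of the 16.

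Infarcted and sham heart cells can be set side by side only with pools from the 75% rule (185 and 30 cells). All 30 sham heart cells also carried the infarcted heart tag, at 41 to 177 counts, so that their origin is in doubt and the ratios hold only if they are sham heart cells. Foxp3 had a ratio of 1.80 (1.03 to 3.44), Ctla4 1.73 (1.22 to 2.52), Tnfrsf18 1.73, Il2ra 1.64 (0.989 to 2.92) and Ikzf2 0.978, and the protease gene Adam19, with counts in 46 infarct heart cells, was at least 3.65-fold higher against the floor (lower limit of the interval 2.91). The homing gene Ccr7 was lower, at 0.494 (0.413 to 0.594). The apolipoprotein gene Apoe was at least 39.6-fold higher and the complement genes C1qa, C1qb and C1qc at least 8.98-, 7.12- and 5.75-fold (lower limits 32.1, 7.25, 5.73 and 4.62), but the top cell of each gene held 99.6% of the Apoe, 100% of the C1qa and C1qc and 98.9% of the C1qb counts. Low ratios were found for Cers6 (0.177), the co-chaperone gene Dnaja4 (0.197), P2rx4 (0.217), Ccl5 (0.239; 2 sham heart cells), Xrcc4 (0.257), Fgf13 (0.266), Zfp868 (0.282) and Amd1 (0.285). Ifng and Areg had 1 count each in sham hearts (ratios 18.04, 3.19 to 717, and 13.02, 2.29 to 519), with 42.4% and 46.5% of the infarct heart counts in the top cell.

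The receptor libraries addressed which clones were present with and without TCR-M transfer. In both transfer libraries 1 clonotype stood out, with the alpha chain TRAV14D-1/TRAJ42 (CDR3 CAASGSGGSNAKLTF) and the beta chain TRBV13-3/TRBJ2-4 (CDR3 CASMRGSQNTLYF). It made up 14.3% of cells with 1 alpha and 1 beta chain in transfer library 1 (926 of 6491; 13.4 to 15.1) and 14.2% in transfer library 2 (916 of 6442; 13.4 to 15.1). In the library without transfer it was in 0 of 1895 such cells, where a count of 0 allows up to 0.158%. Since alpha V gene names differed between the runs, its CDR3 sequences were also sought with any V gene. Without transfer, 0 cells carried its beta CDR3 and 0 its alpha CDR3. Per the labels, TCR-M cells were sorted apart and mixed back, so this share was set by the sort and is no frequency in tissue. The next largest clonotypes had 3 cells in transfer library 1, 5 and 4 in transfer library 2 (TRBV1 with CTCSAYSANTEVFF and TRBV5 with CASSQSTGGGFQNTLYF) and 3 in the library without transfer (TRBV20 with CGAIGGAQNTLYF). At 1895 cells per library, 14.8% of cells in each transfer library and 1.64% without transfer were in clonotypes of at least 2 cells. Leaving out the dominant clonotype gave 1.90% and 1.94% in the transfer libraries at full size.

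**Figure D4:**
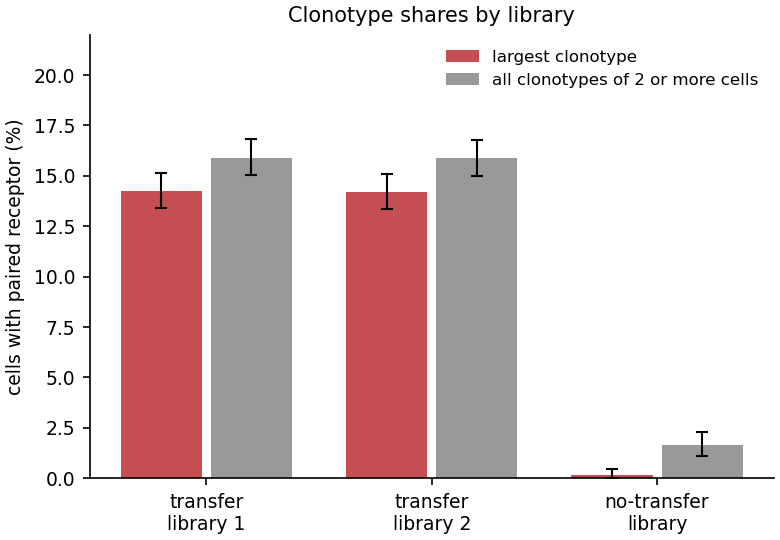
Share of cells with a paired receptor (y axis, percent) that belong to the largest clonotype and to all clonotypes of at least 2 cells, in 2 technical libraries with TCR-M transfer and 1 without; error bars are exact binomial 95% intervals. The largest clonotype holds 14.3% and 14.2% with transfer and 0.158% without.

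Among T cells without transfer, repeated receptors made up a larger share in the infarcted heart than in lymph nodes. In the heart, 9 of 100 cells with a paired receptor (9.0%; 4.20 to 16.4) belonged to 4 clonotypes of at least 2 cells, the largest of which, with 3 cells, was the TRBV20 clonotype. In lymph nodes it was 6 of 1246 after infarction (0.482%; 0.177 to 1.05) and 4 cells after sham surgery (0.811%; 0.221 to 2.06), in 3 and 2 clonotypes. With pools from the 75% rule it was 2 of 13 sham heart cells (15.4%; 1.92 to 45.4) and again 9 of 100 infarcted heart cells. In lymph nodes that rule gave 12 of 1265 after infarction (0.949%; 0.491 to 1.65) and 8 of 497 after sham surgery (1.61%; 0.697 to 3.15). Drawn down to 100 cells, the lymph node shares without that rule were 0.0300% after infarction and 0.152% after sham surgery. No clonotype was shared between the 3 pools, 14 were shared between the transfer libraries, and 0 between a transfer library and the library without transfer. By CDR3 sequences alone, the counts between libraries were also 14 and 0. In beta chain use, TRBV13-3 stood at 16.6% and 16.2% of cells with transfer and 6.65% without, and TRBV5 at 11.6%, 11.8% and 14.1%. Without the dominant clonotype the transfer libraries had 2.77% and 2.35% TRBV13-3 and 13.6% and 13.7% TRBV5. In the alpha chain, TRAV14D-1 stood at 16.7% and 16.2% in the transfer libraries, followed by TRAV6-6 at 4.36% and 4.30%, and without transfer TRAV6N-7 led with 4.59%. Alpha V gene names differed between the runs, with TRAV6-6 in 410 and 409 contigs with transfer and 0 without, and TRAV6D-6 in 0, 0 and 115, so alpha V use is not compared between them.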

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

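Among the tests below, those on sequencing depth, an exchanged label, the muscle covariate and the genes without overlap were chosen after the result was seen. A library was singled out where its gap to the nearest of its group was a large share of the group's range, which chance does in about 1 in 20 groups. Of 242 groups tested 58 held such a library, against 12.1 by chance: 20 of 62 for list scores, 38 of 178 for genes and 0 of 2 for read totals.

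Control 2 stood far below the other 7 controls in 18 list scores (mean log2 CPM), most of them of immune cells and matrix: B and plasma cells (-1.21), MHC class II (2.48), T cells (-1.56), cytotoxic and NK cells (-3.02), dendritic cells (-1.11), neutrophils (-0.26), inflammatory macrophages (-0.91), reparative macrophages (4.12), chemokines (0.28), interferon response (1.90), regulatory T cells (0.68), fibroblast matrix (3.44), matrix proteases (2.73), myofibroblasts (3.72), TGF-beta (3.48), endothelium (4.78), cell cycle (-0.014) and immediate early genes (1.95). Transfer 2 stood low in MHC class II (3.36) and effector T helper genes (1.19).

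Single genes low in control 2 (log2 CPM) were Actg2 (-0.90), Aprt (4.74), Arg1 (-0.26), Arhgap9 (3.37), Capg (3.01), Ccl3 (-3.58), Cd4 (-2.09), Col1a1 (5.74), Ctss (3.98), Fabp5 (3.87), Folr2 (3.86), Gzma (-3.58), Ifi30 (2.98), Il7r (-3.58), Jchain (-2.09), Klrk1 (-3.58), Lum (5.84), Mcm5 (2.13), Meox1 (2.697), Mfsd12 (4.10), Mmp8 (-0.39), Mx1 (-2.66), Nr4a1 (1.76), Oas1a (1.32), Pf4 (2.54), Pycard (2.29), Tgfb1 (4.76), Tgfbi (3.98), Thy1 (1.83) and Tnni2 (0.37). Transfer 2 was low in Cd3e (-3.58), Cxcr3 (-3.58), Meox1 (4.57), Mmp8 (-2.34) and Oas1a (2.20). Flt1 was high in transfer 4 (7.10), Mylpf high in control 6 (3.05) and Lrrn4 low in control 7 (-2.96).

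The first pattern is control 2 apart from the other scars. Depth is argued against, since the other 13 libraries thinned to its read total kept fibroblast matrix scores of at least 5.41, against 3.48 in control 2, and 0 of 14 libraries failed the sex-linked check. A piece with little infarct may explain it and cannot be told apart: an endothelial score above the other controls had been predicted, and it was 4.78, below them, but the premise was wrong, since control 5, with the lowest muscle score (9.05), had a higher endothelial score (5.70) than transfer 2 (5.44), with the highest of the rest (11.76). A label exchanged with a transfer mouse stays open too, as 86.2% of 500 genes in control 2 lay nearer the transfer prediction, against 52.8% in the highest other control and 59.6% in the lowest transfer library. The prediction came from a fit of group and muscle content without control 2. The muscle score of control 2, 12.05, lies beyond the 9.05 to 11.76 of the other libraries, so its prediction is extrapolated. The share therefore cannot decide between an exchanged label and a piece with little infarct. No biological explanation was tested.

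The second pattern is the difference between the groups. With 14 libraries, 2 of 100 splits, the real one included as in all counts of splits here, called at least the real 33 genes. The highest other called 2444, and what the samples of that split share was not tested. As many lists were called in 80 of 100 splits (real 8, median of the others 13, highest other 23). Few splits called as many genes, but 1 of them called far more, so chance is excluded neither for the genes nor for the lists. Without control 2, 1 of 100 splits, the real one itself, called as many genes (real 4534, highest other 0) and 60 of 100 as many lists (real 11, highest other 22). These splits did not repeat the choice of the library left out, which was made after the results were seen. Gene length is argued against, as 65 of 100 splits had as large an absolute rank correlation with fold change (0.0899, highest other 0.354). Muscle content may explain the oxidative phosphorylation part without control 2, whose median went from 0.92 to 0.044 with the covariate. For the reparative macrophage part the covariate cannot decide. With it, 5 members were lower without control 2, but 0 over all 14 libraries, where the median was 0.06. A covariate from gene scores may also not remove all muscle content. The transfer itself, and preparation batches, which the labels do not give, stay open.

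The third pattern is the high level of heat shock and immediate early genes in heart T cells, with a ratio of the stress list of 4.54 (4.47 to 4.62) over lymph node T cells after infarction. In infarcted over sham hearts the list stood at 0.776 (0.748 to 0.806, counting error only), but each pool is 1 sample and all 30 sham heart cells also carried the infarcted heart tag above its threshold, so infarction cannot be told apart from other causes. Tissue digestion and a difference between tissues were not tested apart, since every heart pool was digested.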

How the results depend on the processing

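The robust fit, the muscle covariate, the fits of DESeq2 and limma-voom without control 2, control 2 and transfer 2 left out together, and other clustering genes were chosen after the data were seen. The count of scar genes, 33, was 0 without scaling, 4 without a filter, 69 with 1 CPM in 6 libraries, 1051 with DESeq2, 20 with limma-voom, 4717 with quality weights, 269 at an adjusted p of 0.1, 13 with an absolute log2 change of at least 1, and 0 to 4534 with 1 library left out. It was 3185 without control 2 and transfer 2, 654 with the muscle covariate (68.7% higher, against 48.5%), 872 with the covariate and without control 2, 1188 when the covariate was scored over all 14 libraries, and 5633 (DESeq2) and 4609 (limma-voom) without control 2. The 20 named genes kept their sign in every setting run, but they had been picked as the most extreme called genes of these same libraries. Of the 20, 0 kept their call without scaling, with the replicate block, or without control 8, transfer 3 or transfer 4. Lists called, 8, were 13 without a filter, 6 to 13 with 1 library left out, and 0 with an estimated correlation, with or without control 2, and 0 with fry. With the replicate block 0 genes passed in edgeR, with 2760 at an unadjusted p under 0.05, and 18 lists. Deviations of samples of the same number correlated at -0.29, 0.86, -0.21, -0.23, 0.71 and 0.23, and transfers 2 and 5 correlated best with the control of their own number. As 3 of 6 correlations were negative, the numbers were not taken to pair the samples.

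A list counts as turned when the direction of its test changed and it was called in all libraries or in the alternative; without a call in either it counts as unchanged. With the muscle covariate this held for myofibroblasts (0.43), matrix proteases (0.47), fatty acid oxidation (-0.10), oxidative phosphorylation (-0.042) and cell cycle (0.030), and with the covariate and without control 2 for contractile genes (0.0037) and fatty acid oxidation (0.053), whose medians stayed positive. Lists without a call turned too, among them with the covariate Treg (0.27), reparative macrophages (0.06), dendritic cells (0.29), interferon response (0.22) and chemokines (0.46), and without control 2 fibroblast matrix (0.40) and TGF-beta (0.13). The medians of inflammatory macrophages (0.05), lymph node stroma (0.89) and skeletal muscle (0.31) also changed sign with the covariate. Over all settings, list calls stayed as they were in 680 cases, were gained in 48, lost in 43 and turned in 7; gene calls stayed in 2087, were gained in 313 and lost in 286. Of the ratios 73 stayed within their interval and 2 moved.

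With the 75% hashtag rule sham hearts had 30 cells in place of 0, and the Treg-like share of infarcted hearts was 2.16%. It was 1.66% with other clustering genes, 39.2% at resolution 0.5 (10.4% in infarct lymph nodes) and 0.552% at 1.5. A Foxp3 UMI in place of the cluster gave 5.39% and 6.17% in sham and infarct lymph nodes. Foxp3 shares for sham lymph nodes, infarct lymph nodes and infarcted hearts were 1.67%, 2.63% and 4.49% at 1000 UMIs and 3.41%, 3.76% and 7.74% at 2000, so depth limits them. With pools from the 75% rule, the infarcted heart share was 7.14% at 1000 UMIs and 7.60% at 2000. Tetramer shares in that order were 3.32%, 5.18% and 10.5% at the 95th percentile and 0.138%, 0.105% and 0% at the highest percentile tried.

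The largest clonotype of transfer libraries 1 and 2 held 11.5% and 11.2% by beta chain alone, 10.0% and 9.90% by deposited identifiers, and 26.1% and 25.3% with at least 5 UMIs per contig. Expanded shares, with the library without transfer last, were 12.8%, 12.6% and 3.12%, 11.1%, 10.8% and 2.36%, and 26.4%, 25.7% and 0.356%. These settings change which cells are counted; for the other changes the cause was not tested.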

Other observations

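The genes below, the test of genes without overlap and the test of the receptor segment were chosen after values were seen. With control 2 left out, some of the genes with the smallest p in edgeR lay lower in all 6 transfer libraries than in each of the other 7 controls. No list test was made on them. They include the oxidase subunit gene Cyba (log2 fold change -1.52 ± 0.16), the adaptor genes Card9 (-1.48 ± 0.17) and Lat2 (-2.82 ± 0.32), the lysosomal nuclease gene Dnase2a (-1.39 ± 0.14), the protease inhibitor gene Cstb (-1.80 ± 0.20) and the lipid droplet gene Plin2 (-1.74 ± 0.20). Above all 7 controls were the phosphatase gene Inpp4b (0.92 ± 0.11), the peptide-processing gene Cpe (1.01 ± 0.12), the survival gene Bcl2 (0.66 ± 0.09) and the glutamate transporter gene Slc1a1 (1.72 ± 0.22). Over all 14 libraries only Bcl2 of these passed (adjusted p = 0.0173 in edgeR), and the others had adjusted p between 0.0524 (Dnase2a, Plin2) and 0.0919 (Lat2). Control 2, left out above, lay below the transfer mean in each of the 6 lower genes, with Lat2 at -1.12 log2 CPM against 3.08. It lay near the transfer mean for Inpp4b (4.94 against 4.99), Cpe (8.38 against 8.39) and Slc1a1 (2.10 against 2.36). Bcl2 went the other way, at 3.91 in control 2, against a mean of 3.94 in the other controls and 4.59 after transfer.

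Of 16117 genes, 1308 had groups that did not overlap without control 2, 429 above and 879 below. That is 8.12%, where chance gives 0.117%. Of 100 splits, 1 gave as many, the real one, and the highest other gave 66. All splits were made without control 2, so they did not repeat the choice of the library left out. Of the 4534 genes called without control 2, 684 were also called with the muscle covariate, 282 higher and 402 lower, and 0 changed sign.

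The beta segment of the transferred receptor was sought in scar reads, on the hypothesis that transferred cells may make up a large part of them. Trbv13-3 took 0.225 ± 0.161% of Trbv reads in controls (mean ± SD, n = 8) and 0.414 ± 0.769% after transfer (n = 6), with a two-sided exact permutation p of 0.775 over 3003 splits. The transfer mean rests on transfer 4, at 1.97% (1.5 of 76 reads), while the other transfer libraries lay at 0 to 0.210%. Trbv13-2 held a median of 83.3% of the Trbv reads of a scar library. In the receptor library without transfer, TRBV12-2+TRBV13-2 stood at 8.13% of paired cells, so Trbv reads of scars may not reflect receptor use. With 5.5 and 2.25 reads of the segment in the groups, the counts are too few to decide.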
